A study of Mus musculus with 21 samples.

How the data were processed

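Messenger RNA was measured in 21 libraries of 7 mouse glioma stem-like cell lines, 4 IDH1 mutant and 3 IDH1 WT, with 3 libraries per line that the labels call biological replicates. Per the labels' protocols, polyA RNA was captured, rRNA was removed, and strand-specific libraries were sequenced as read pairs on a NovaSeq instrument. Per the submitters' processing notes, the tool was HISAT2 and the genome build mm39, while the read counter, the annotation release and the use of strand in counting are not given in the sources used here.

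The deposited values are FPKM of 54532 genes, fragments scaled by gene length and library size, made by the authors. The gene coordinates in the file are those of GRCm38 and not of the build in the processing notes: 54495 gene IDs were found in the GENCODE annotation of GRCm38 and 53585 had the same chromosome, start and end there. Coordinates are therefore given as GRCm38. In the file, 27 gene symbols had been turned into dates and were restored by gene ID, and Cgas is listed under its older symbol.

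FPKM times gene length was a whole multiple of 1 step per library for all values under 1000 fragments, within a tolerance of 0.05 fragments, so whole fragments could be recovered. They gave 15011668 to 21966351 fragments per library. The library size behind the FPKM was 0.957 to 1.05 times the gene total, and its differences between libraries were within 1.451% of TMM factors computed from the recovered fragments, so the deposited FPKM already hold a scaling of this kind. Counting intervals are exact Poisson intervals at 95% and cover counting error only. No pair of libraries of a line agreed within sampling noise (chi-square per gene 3.79 to 26.9), so none was treated as a duplicate.

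Tests were run on log2(FPKM + 0.5) of line means in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with trend and robust), on genes with a line-mean FPKM of at least 0.5 in at least 3 of the 7 lines, with Benjamini-Hochberg adjusted p under 0.05. The fold changes are on this log2 scale. The p-values measure the spread between lines, and lines that share a number in their name (144, 496) could come from the same animal, which the labels do not say. Cgas was also tested by an exact two-sided permutation of the difference of means over the 35 splits of the lines. Of 28 gene lists, 25 were of pathways, genes or cell types, and those with at least 5 tested members entered limma camera with an inter-gene correlation of 0.01, camera with an estimated correlation and fry. fry asks whether a list's genes move on balance in the same direction, without comparing them with other genes. Differences between lines of a genotype were tested by a limma F test over the libraries, in which libraries of a line are its replicates and may differ only technically.

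Groups, tests, gene lists, the naming rule and most alternatives were fixed before the data were examined. Named were Cgas and Idh1, the 12 genes in each direction with the largest log2 change among those that passed, did not overlap between genotypes and had no predicted or clone symbol, or the first 6 by p where fewer than 6 qualified. Of each list the members that passed were named, at most 6, or the 2 with the smallest p where none passed, and for cell type lists also the most abundant gene, except that a few genes this rule names are not reported here. Genes named beyond this rule, such as those beside the Y-linked genes and whole chromosomes, were chosen after their values were seen.

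Alternatives were other pseudocounts (0.1 and 1), no filter, a stricter filter (mean FPKM at least 2), rescaling to TPM, median-of-ratios scaling, quantile normalization, eBayes without trend or robust, protein-coding genes only, fits over 21 libraries with and without the line as a random effect or the replicate number as a block, lines sharing a number averaged, line weights, and leaving out each line or each replicate. Added after seeing the data were limma voom on the recovered fragments summed per line, leaving out both PIC496 lines, autosomal genes only, and leaving out each line with the 13379 tested genes kept. Depth limits Cgas most in PIC496-4, with 9 to 22 fragments per library. On simulated lines with the measured spread, in which 200 of 13379 genes were changed, the limma fit recovered 76% of genes changed by 2 on the log2 scale and 33.67% of those changed by 1, with a mean of 4 false calls per run. The simulated noise was drawn independently for each gene and line. It left out the shifts of whole chromosomes and the likeness of lines seen here, so these values may not hold for the real lines. Figures were drawn with matplotlib 3.10.9.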

Results

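Gene expression was measured by mRNA sequencing in 7 mouse glioma stem-like cell lines, which are cultures grown from brain tumours of genetically engineered mice in stem cell medium with growth factors at low oxygen. The labels give 4 lines as IDH1 mutant (PIC144-1, PIC144-3, PIC496-3 and PIC496-4) and 3 lines as IDH1 WT (PC134-0, PC308-1 and PC326-1), each with 3 libraries, 21 in all. IDH1 encodes a cytosolic isocitrate dehydrogenase whose tumour mutants make 2-hydroxyglutarate in place of 2-oxoglutarate. Whole fragments recovered from the deposited FPKM gave 15011668 to 21966351 fragments per library. The genotype belongs to the line, so a line was 1 replicate, with the mean of its 3 libraries as its value (n = 4 IDH1 mutant and n = 3 IDH1 WT lines).

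The question named by the series is the level of Cgas in IDH1 WT and IDH1 mutant glioma cells. Cgas encodes cyclic GMP-AMP synthase, the enzyme that senses double-stranded DNA in the cytosol and signals through STING. The gene (ENSMUSG00000032344) lies on chromosome 9 from 78430526 to 78443237 on the minus strand in GRCm38 coordinates. Cgas was measured at 1.09 ± 1.03 FPKM in the IDH1 mutant lines (SD, n = 4) and at 3.40 ± 0.447 FPKM in the IDH1 WT lines (SD, n = 3). Each IDH1 mutant line lay below each IDH1 WT line. On the log2(FPKM + 0.5) scale the difference was -1.51 (SE 0.458), a 2.85-fold lower level with a 95% interval of 1.37 to 5.95.

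The IDH1 mutant lines differed widely among themselves in Cgas. PIC496-4 had the lowest level at 0.229 ± 0.0848 FPKM (SD, 3 libraries), followed by PIC144-1 at 0.502 ± 0.0946 and PIC496-3 at 1.07 ± 0.135 FPKM. PIC144-3 reached 2.55 ± 0.340 FPKM, close to the lowest IDH1 WT line, PC308-1, at 3.06 ± 0.149 FPKM. PC326-1 and PC134-0 had 3.24 ± 0.105 and 3.91 ± 0.291 FPKM. These values rest on 51 fragments in PIC496-4 and 825 in PC134-0, summed over the 3 libraries of each line. The 95% counting interval of PIC144-3 ended at 2.81 FPKM and that of PC308-1 began at 2.83 FPKM, so these neighbouring lines were barely apart.

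An exact two-sided permutation test over the 35 splits of the 7 lines gave p = 0.0571 for Cgas, above the threshold of 0.05, where the smallest p this design allows is 0.0286. The limma p for Cgas was 0.0113 before adjustment and 0.2998 after Benjamini-Hochberg adjustment over all genes, so Cgas did not pass the genome-wide test. Without both PIC496 lines, a setting chosen after seeing the data, the log2 difference was -1.16 and the limma p before adjustment 0.0541.

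**Figure D1:**
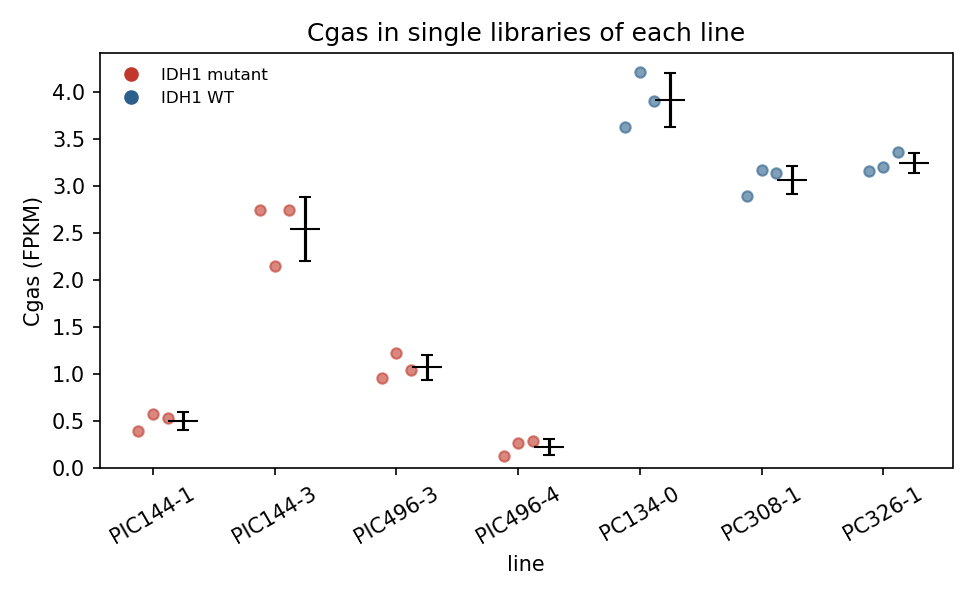
Cgas in FPKM (vertical axis, linear) in single libraries of the 7 lines (horizontal axis), IDH1 mutant in red and IDH1 WT in blue. The black mark and bar beside each line give the mean and SD of its 3 libraries, from 0.229 FPKM in PIC496-4 to 3.91 FPKM in PC134-0.

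Idh1 itself was measured at 121 ± 9.18 FPKM in the IDH1 mutant lines (SD, n = 4) and 84.4 ± 5.48 FPKM in the IDH1 WT lines (SD, n = 3), with no overlap between the lines. The gene (ENSMUSG00000025950) lies on chromosome 1 from 65158616 to 65186500. The log2 difference was 0.52 (SE 0.126). The exact permutation p for Idh1 was 0.0286, the smallest the design allows, and the limma p adjusted over all genes was 0.244. FPKM per gene do not show the mutation, so this level is not a check of the genotype labels.

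Across the transcriptome, the comparison asked which genes differed between IDH1 mutant and IDH1 WT lines. Of 13379 genes tested, 15 changed at a limma adjusted p under 0.05, with 3 higher and 12 lower in the IDH1 mutant lines. The lower genes included 3 on the Y chromosome: Ddx3y, an RNA helicase, Eif2s3y, a translation initiation factor subunit, and Kdm5d, a histone demethylase. Autosomal genes that fell were Igsf21, a synaptic adhesion protein, Mfap2, a protein of extracellular microfibrils, and the nervous system genes Grik3, a kainate receptor subunit, and Cntn4, a contactin. Cox4i2 and Ndufa4l2, which encode mitochondrial proteins induced at low oxygen, and Cdo1, cysteine dioxygenase, fell as well.

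Igsf21 (ENSMUSG00000040972, chromosome 4 from 140026846 to 140246784) was at 0.0351 ± 0.0415 FPKM in the IDH1 mutant lines and 7.73 ± 1.97 FPKM in the IDH1 WT lines, a log2 change of -3.92 (SE 0.211, limma adjusted p = 0.00134). Mfap2 (ENSMUSG00000060572, chromosome 4 from 141010418 to 141015984) was at 0.430 ± 0.212 and 11.2 ± 2.19 FPKM, with a log2 change of -3.73 (SE 0.241, limma adjusted p = 0.00268). Cox4i2 fell by 3.63 on the log2 scale, from 9.46 ± 2.70 FPKM in the IDH1 WT lines to 0.308 ± 0.264 FPKM in the IDH1 mutant lines. Ndufa4l2 was at 21.1 ± 12.2 FPKM in the IDH1 WT lines and 1.33 ± 0.437 FPKM in the IDH1 mutant lines. Grik3, Cdo1 and Cntn4 had log2 changes of -2.75, -2.22 and -1.94. Pcdhgb6, a member of the gamma protocadherin cluster on chromosome 18, had a log2 change of -4.08, but the genes of this cluster share their last exons, so its value is uncertain. These log2 changes are of FPKM + 0.5 and understate the change of genes near 0.

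Among the genes that rose, Fbxo2, the substrate-binding part of a ubiquitin ligase for glycoproteins, was at 25.3 ± 2.86 FPKM in the IDH1 mutant lines and 8.004 ± 1.17 FPKM in the IDH1 WT lines (log2 change 1.59, SE 0.151, limma adjusted p = 0.0152). Rps6ka1, a kinase downstream of ERK, was at 15.6 ± 1.89 and 6.20 ± 0.982 FPKM (log2 change 1.27, SE 0.157, limma adjusted p = 0.0418). The next higher genes did not pass the limma test: the long noncoding RNA Pantr1 (log2 difference 1.12), Pgd of the pentose phosphate pathway (0.85), Pmvk of the mevalonate pathway (0.85) and the lipid kinase Pip4k2a (0.75), with adjusted p from 0.0988 to 0.110. The other called genes were the predicted genes Gm4870, lower, and Gm48667, higher, which are outside the naming rule and were chosen after their values were seen. Igsf21, Mfap2, Grik3, Fbxo2, Rps6ka1 and Pgd all lay on chromosome 4 between 125490700 and 149166771. They may therefore not be separate changes, and whether a shared segment plays a part was not tested. At an unadjusted limma p under 0.01, chromosome 4 held 12 lower genes (16.54 expected) and 19 higher (11.49 expected). Neither count passed (Fisher's exact test, adjusted p = 0.5277 and 0.1335).

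The count of 15 was not stable when a line was left out. It was 0 without PC134-0 (698 genes at an unadjusted p under 0.05), 1 without PC326-1, 4 without PIC144-1, 5 without PIC496-4 and 29 without PC308-1. Without any of the 3 IDH1 WT lines, 5 of the 15 genes, Igsf21, Kdm5d, Grik3, Cntn4 and Gm4870, no longer met the filter of 3 lines and were not tested. With the 13379 genes kept, chosen after seeing the data, the count was 3 without PC134-0 (742 genes at an unadjusted p under 0.05), 3 without PC326-1 and 48 without PC308-1, and 4 to 16 without an IDH1 mutant line. Fewer lines also make these tests weaker. Limma voom on the recovered fragments, chosen after seeing the data, called 0 genes (1643 at an unadjusted p under 0.05). With lines sharing a number averaged, 6 genes were called, 0 higher and 6 lower, of which 2 were among the 15, Igsf21 and Mfap2, and Fbxo2 and Rps6ka1 no longer passed. At an unadjusted limma p under 0.05 there were 1719 genes, 12.85% of those tested. In 13.18% of genes the line values did not overlap between genotypes, where chance gives 5.714% on average if the lines are independent. PC134-0 and PC326-1, with a correlation of 0.983, put this independence in doubt, and the spread of the share over other splits of the lines was not tested. Most other splits gave fewer genes at an unadjusted p under 0.05, but some gave more, up to 2241. The 13.18% therefore cannot be read as an effect of genotype.

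**Figure D2:**
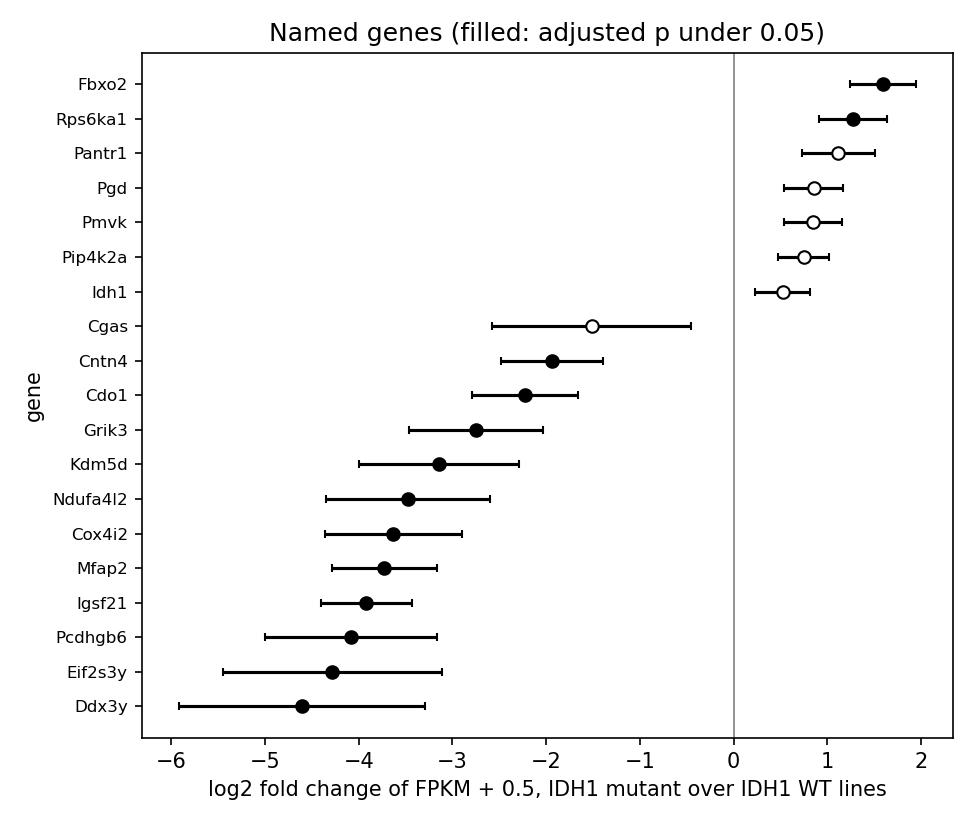
Log2 fold change of FPKM + 0.5 (horizontal axis, IDH1 mutant over IDH1 WT lines, bars are 95% intervals of limma) for each named gene (vertical axis). Filled points passed an adjusted p under 0.05, and open points, with Cgas at -1.51 and Idh1 at 0.52, did not.

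The Y-linked genes separated the lines of the mutant group as well. Ddx3y was at 27.1, 10.2 and 29.1 FPKM in PC134-0, PC308-1 and PC326-1, at 0.580 and 1.39 FPKM in PIC144-1 and PIC144-3, and had 0 fragments in both PIC496 lines. Xist, the RNA of the inactive X chromosome, was at 8.11 ± 1.61 FPKM in PIC496-3 and 15.6 ± 3.57 FPKM in PIC496-4 (SD, 3 libraries each), against at most 0.0139 FPKM in the other 5 lines. Of the list of X-inactivation and Y-linked genes, 4 were tested, 3 passed over all genes and 4 were lower adjusted over the list alone. Without both PIC496 lines 4 genes changed, and among autosomal genes only 12 changed, both settings chosen after seeing the data.

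**Figure D3:**
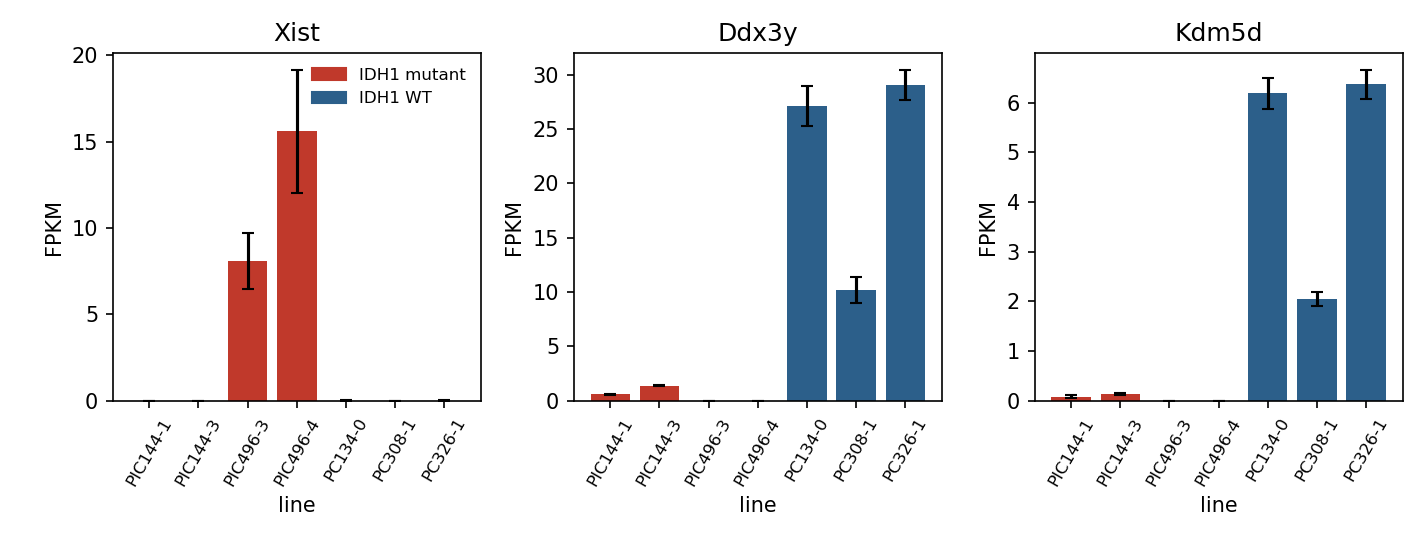
Xist, Ddx3y and Kdm5d in FPKM (vertical axes, linear from 0) in the 7 lines (horizontal axes), with bars for the mean and error bars for the SD of 3 libraries. Xist stands at 8.11 and 15.6 FPKM in PIC496-3 and PIC496-4, and Ddx3y at 10.2 FPKM or more in the IDH1 WT lines.

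Gene lists were compared next, with limma camera at a preset inter-gene correlation of 0.01. Interferon-stimulated genes lay lower in the IDH1 mutant lines, with negative log2 differences for 21 of 23 tested members and a median of -0.78 (camera adjusted p = 1.46e-05). With an estimated correlation the list did not pass (adjusted p = 0.543), and the fry p was 0.0933. Over all genes 0 members passed in limma, with 6 lower at an unadjusted p under 0.05, and 2 were lower adjusted over the list alone. The antiviral genes Ifit2 and Rsad2 were at 0.644 ± 0.437 and 0.638 ± 0.444 FPKM in the IDH1 mutant lines, and at 4.70 ± 2.19 and 4.13 ± 2.40 FPKM in the IDH1 WT lines. The genotypes overlapped in the list as a whole: its median deviation was 1.12 in PC134-0, 0.26 in PIC144-3, 0.23 in PC326-1, 0.04 in PC308-1 and -0.81 in PIC496-4. Without PC134-0 the list's median difference was -0.37.

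Genes of double-stranded RNA sensing had a median log2 difference of -0.70 over 9 tested members (camera adjusted p = 0.0110, adjusted p = 0.543 with an estimated correlation, fry p = 0.0154). The fry p-values are not adjusted over the 19 lists. Only 2 lists had one under 0.05, neuronal genes (fry p = 0.0403) and double-stranded RNA sensing. In this list 1 member was lower adjusted over the list alone, Zcchc3, a cofactor of RNA and DNA sensors, at 0.652 ± 0.702 FPKM in the IDH1 mutant and 6.502 ± 0.517 FPKM in the IDH1 WT lines, and it did not pass over all genes (limma adjusted p = 0.110). The call of this list ended without PC134-0 (adjusted p = 0.0772) and without PC308-1 (adjusted p = 0.0776). Oasl1 was at 0.211 ± 0.04997 and 1.31 ± 1.16 FPKM. Zcchc3 lies near Cox4i2 on chromosome 2, with starts at 152411955 and 152754173. These 2 genes may therefore not be separate changes, and whether a shared segment plays a part was not tested. Class I antigen presentation had a median of -0.40 over 20 members (camera adjusted p = 0.0110, adjusted p = 0.543 with an estimated correlation), with B2m at 85.8 ± 35.2 and 171 ± 68.9 FPKM and Tap1 at 1.09 ± 0.867 and 2.31 ± 0.351 FPKM, and no member passed. The genotypes overlapped in class I antigen presentation, with a median deviation of 0.30 in PIC144-3, above PC326-1 (0.28) and PC308-1 (-0.11). The call of class I antigen presentation ended without PIC144-1 (adjusted p = 0.0520), without PC134-0 (0.0565) and without both PIC496 lines (0.144), the last chosen after seeing the data.

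The cytosolic DNA sensing list, which holds Cgas, did not differ as a list. Of its 15 tested members 8 had positive and 7 negative differences, the median was 0.05 and the mean -0.06, opposite in sign, and the camera adjusted p was 0.930. Cgas and Rnaseh2c, a subunit of ribonuclease H, had the smallest p of its members, and Rnaseh2c was at 17.5 ± 1.053 FPKM in the IDH1 mutant and 13.5 ± 2.15 FPKM in the IDH1 WT lines. Sting1, listed as Tmem173, was at 40.8 to 54.4 FPKM in the IDH1 mutant lines and 55.5 to 60.4 FPKM in the IDH1 WT lines. Trex1 was listed at 0 in every library and shares its strand and position with Atrip, and whether this overlap caused the 0 was not tested. Chemokines and cytokines (median -0.21, adjusted p = 0.726) did not pass, with Cxcl10 at 1.45 ± 1.81 and 7.44 ± 6.66 FPKM and Tgfb3 at 13.1 ± 1.71 and 8.69 ± 6.32 FPKM. Of class II antigen presentation only 2 members were tested, H2-Ab1 and H2-DMa, with log2 differences of -1.23 and -0.34.

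Metabolic and proliferation lists lay slightly higher in the IDH1 mutant lines by camera at the preset correlation, and none of these calls held with an estimated correlation (adjusted p = 0.543 for each). Proliferation had positive differences for 23 of 30 members and a median of 0.21 (camera adjusted p = 0.00717), with the centromere genes Cenpa (log2 difference 0.46) and Cenpe (0.35) first by p. The list of 2-oxoglutarate, glutamate and branched-chain amino acid metabolism had a median of 0.29 over 28 members (camera adjusted p = 0.0159), led by Idh1 and Glud1, glutamate dehydrogenase (53.4 ± 7.05 and 41.0 ± 4.33 FPKM). Pyrimidine synthesis had a median of 0.24 over 17 members (camera adjusted p = 0.0159), with Cda (0.97) and Tk1 (0.55) first by p. The genotypes overlapped in pyrimidine synthesis, with a median deviation of -0.18 in PIC144-3, below the lowest IDH1 WT line, PC134-0 (-0.17). In each of these lists 0 members passed over all genes or adjusted over the list alone in limma, with 4, 2 and 2 members higher at an unadjusted p under 0.05. Without PC308-1 the calls of proliferation (adjusted p = 0.305), the 2-oxoglutarate list (0.119) and pyrimidine synthesis (0.134) ended, as did those of the 2-oxoglutarate list (0.164) and pyrimidine synthesis (0.101) without PIC496-4. Of 28 alternatives, the call ended under 7 for pyrimidine synthesis, 6 for the 2-oxoglutarate list and 4 for proliferation.

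The other pathway lists did not pass camera. Silencing of endogenous retroviruses had a median of 0.11 (adjusted p = 0.0510), with the antiviral protein Zc3hav1 at 8.87 ± 2.28 FPKM in the IDH1 mutant and 13.8 ± 0.495 FPKM in the IDH1 WT lines, and the histone methyltransferase Setdb1 at 14.05 ± 0.576 and 11.3 ± 0.683 FPKM. DNA methylation and TET genes (adjusted p = 0.862, with Tdg and Zbtb38 first by p), histone demethylases (0.933, Kdm5c and Kdm3a), hypoxia-response genes (0.563, Lox and P4ha2), p53 target genes (0.910, Tnfrsf10b and Gtse1) and glioma driver genes (0.862, Idh1 and Pik3r1) had medians between -0.01 and 0.09. DNA methylation and TET genes and p53 target genes had medians of -0.01 and -0.00117 with positive means and tests, and histone demethylases a median of 0.02 with a mean of -0.00219. Silencing of endogenous retroviruses passed under 8 of 28 alternatives (lowest adjusted p = 0.00946, with no filter), among them without PIC144-3 (0.0180), without PIC496-3 (0.0279) and without replicate 1 (0.0250). Pik3r1, the regulatory subunit of PI3 kinase, was at 26.7 ± 8.80 and 53.9 ± 7.17 FPKM and did not pass over all genes.

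Cell type lists were compared for the identity of the cultures and for other cells in them. Oligodendrocyte progenitor genes lay lower in the IDH1 mutant lines (median -0.66 over 14 members, camera adjusted p = 0.0159), as did neuronal genes (median -0.61 over 8 members, camera adjusted p = 0.0110), and both had adjusted p = 0.543 with an estimated correlation. The genotypes overlapped in both lists. The median deviation of oligodendrocyte progenitor genes was 0.60 in PIC496-3, above PC134-0 (0.27) and PC326-1 (0.04). That of neuronal genes was 0.24 in PIC144-3 and 0.28 in PIC496-3, above PC308-1 (0.14) and PC326-1 (0.19), and -1.16 in PIC496-4. Pdgfra was at 104 FPKM in PC308-1 and at 12.4 FPKM or less in the other lines, while Olig1, the most abundant of its list, was at 482 ± 173 and 483 ± 119 FPKM. The neuronal genes Syp and Tubb3 were at 0.354 ± 0.221 and 6.64 ± 4.46 FPKM in the IDH1 mutant and 1.27 ± 0.219 and 21.9 ± 9.88 FPKM in the IDH1 WT lines, and Map2 was the most abundant of that list at 24.1 ± 7.05 and 35.8 ± 7.24 FPKM. Neural stem and progenitor genes (median -0.45, adjusted p = 0.0863), astrocyte genes (-0.34, 0.162) and mesenchymal glioma genes (0.22, 0.115) did not pass. The call of oligodendrocyte progenitors ended without PIC144-1 (adjusted p = 0.0657), PIC496-4 (0.101) or PC308-1 (0.411), and that of neurons without PIC496-4 (0.0524) or PC308-1 (0.0552). Without PIC496-3 the neural stem (0.0277), astrocyte (0.0430) and mesenchymal lists (0.0279) passed, and the mesenchymal list also without PIC496-4 (0.0247). In these lists Hes5 and Nes had log2 differences of -2.03 and 0.49, Apoe and Atp1b2 of -3.02 and -1.42, and Anxa2 of 0.36. Apoe, the lipid carrier, was lower adjusted over the list alone, at 1.56 ± 0.807 and 16.7 ± 7.76 FPKM, and missed the limit over all genes (limma adjusted p = 0.0709). The most abundant genes of these lists were Vim at 543 ± 102 and 422 ± 80.8 FPKM, Sparcl1 at 337 ± 198 and 345 ± 97.8 FPKM, and Lgals1 at 302 ± 109 and 261 ± 81.8 FPKM.

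Markers of mature oligodendrocytes, microglia, endothelial cells, fibroblasts and T or NK cells were too few above the filter to test as lists. Cnp and Cldn11 had log2 differences of -1.02 and -0.24, Cd68 of -0.43, Egfl7 and Flt1 of 0.48 and -0.16, and Col1a1 and Col3a1 of 0.63 and 0.89, and none passed over all genes. The microglia gene C1qa was listed at 0 in every line. Dcn, a fibroblast gene, was at 10.4 FPKM in PIC144-1 and at 0.0441 FPKM or less elsewhere, and the T and NK cell gene Klrb1c was at 0.943 FPKM or less in every line. Of the lists of technical interest, mitochondrially encoded genes had a median of -0.07 and a mean of 0.05, with mt-Co1 at 3909 ± 480 and 5536 ± 175 FPKM and mt-Atp6 at 35.2 ± 1.49 and 25.2 ± 8.502 FPKM, and immediate early and stress genes had a median of -0.17, with Dusp1 at 14.1 ± 5.09 and 8.08 ± 1.37 FPKM and Ddit3 at 24.7 ± 6.48 and 39.2 ± 10.6 FPKM.

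**Figure D4:**
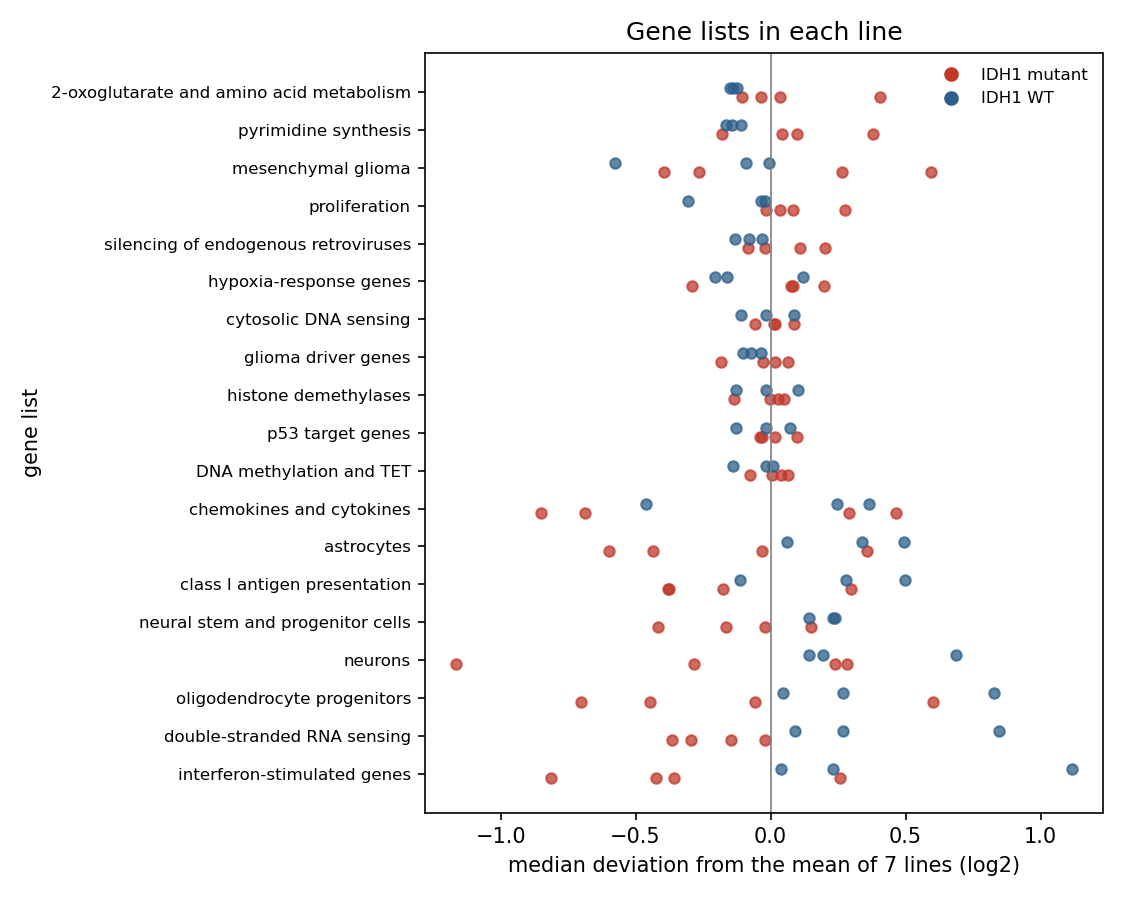
Median deviation from the mean of 7 lines (horizontal axis, log2) of the tested members of each of 19 gene lists (vertical axis), 1 point per line, IDH1 mutant in red and IDH1 WT in blue. Interferon-stimulated genes range from -0.81 in PIC496-4 to 1.12 in PC134-0, with PIC144-3 among the IDH1 WT lines.

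Lines of the same genotype were compared with each other to see how far they differ beyond the spread between libraries of a line. In a limma F test over the libraries, 10801 of 13379 genes (80.73%) differed between the 4 IDH1 mutant lines and 8215 (61.4%) between the 3 IDH1 WT lines. The 15 genes called between genotypes rest instead on the spread between lines. The counts therefore differ in their error and cannot be compared with each other. Cgas differed between the IDH1 mutant lines (limma adjusted p = 2.50e-11) and, less clearly, between the IDH1 WT lines (limma adjusted p = 0.0450). The correlation of log2 values across genes averaged 0.933 between IDH1 mutant lines, 0.954 between IDH1 WT lines and 0.927 between genotypes, and was highest for PC134-0 and PC326-1 at 0.983. Genes are not independent replicates in these correlations. Without PC308-1 the count between the IDH1 WT lines was 2523.

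Expression of whole chromosomes also differed between lines. Genes of chromosome 12 had a median deviation of -0.53 in PC134-0 and -0.54 in PC326-1, of 0.52 in PC308-1, and of 0.28 and 0.29 in PIC496-3 and PIC496-4, with bootstrap standard errors of 0.0257 or less. Chromosome 13 lay at 0.33 and 0.28 in PC134-0 and PC326-1 and at -0.27 in PC308-1, and chromosome 18 at -0.36 in PIC144-1.

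**Figure D5:**
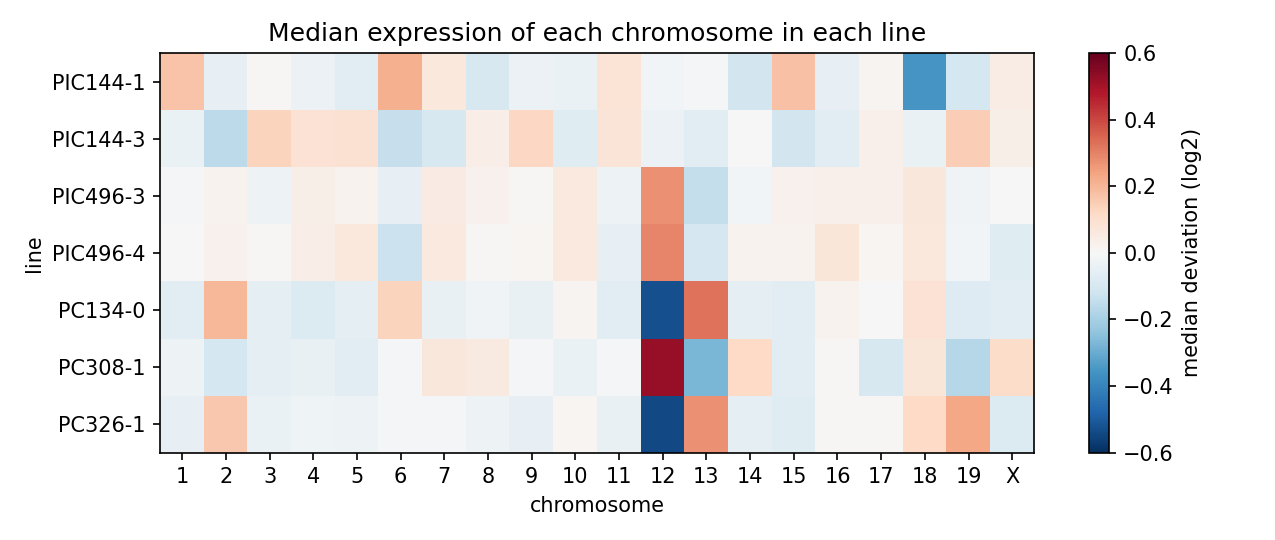
Median deviation of expressed genes from the mean of 7 lines (color, log2) for each chromosome (horizontal axis) in each line (vertical axis). Chromosome 12 stands at -0.53 and -0.54 in PC134-0 and PC326-1 and at 0.52 in PC308-1.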

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

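The tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the samples. Of 87 sets of values of the 4 IDH1 mutant lines, 3 held a line far from the other 3 by the gap between neighbouring values over the range, which chance gives in about 1 of 20 sets. For Ndufa4l2 this was PIC144-3 (ratio 0.893), for Zc3hav1 PIC144-1 (0.847), the lowest, and for Egfl7 PIC496-3 (0.857), the highest. No explanation was tested for these.

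Cgas lay lower in the IDH1 mutant lines. The choice of scaling is argued against as the whole cause, since the log2 difference was -1.94 with TPM, -1.51 with median-of-ratios and -1.36 with quantile normalization (limma p before adjustment 0.0125, 0.0112 and 0.00999), while a change in total RNA per cell was not measured. The TPM value also reflects a smaller weight of the added 0.5, since TPM values are larger than FPKM. Loss of the chromosome 9 region around Cgas would lower its neighbours, and the 36 tested genes within 5 Mb had a median of 0.055 (bootstrap SE 0.0479), so loss of the whole region is argued against, while loss of Cgas alone was not tested. Female sex does not account for the 0.502 FPKM of Cgas in PIC144-1, which had Y-linked fragments and Xist at 0.00567 FPKM, while for both PIC496 lines it cannot be told apart from the genotype, since no IDH1 WT line had Xist above 0.0139 FPKM, and without them the difference was -1.16 (SE 0.481, limma p before adjustment 0.0541). An effect of the IDH1 genotype may remain, as a hypothesis, beside differences between lines.

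Interferon-stimulated genes lay lower in the IDH1 mutant lines as a list. Without PC134-0 the median difference was -0.368 (camera adjusted p = 0.0115 at the preset correlation, camera p = 0.291 with an estimated correlation). With all 7 lines the list does not pass with an estimated correlation either (adjusted p = 0.543, fry p = 0.0933), so whether PC134-0 alone makes the difference stays open. Microglia or macrophages in the IDH1 WT cultures would bring their markers, and the highest median of 18 markers in an IDH1 WT line was 0.00197 FPKM, which argues against a large share of such cells. A small share is not excluded. Of these markers 2 were above the filter, and their median deviation was highest in PC134-0 (1.34), where Cd68 was at 5.05 FPKM. Of the 35 splits of the lines, 5 called at least as many lists as the 8 of the real split, and the highest other split called 12, so chance cannot be excluded for the count of lists.

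Y-linked genes were low in all 4 IDH1 mutant lines. A female origin of both PIC496 lines would give Xist and no Y-linked fragments, and Xist was at 8.11 FPKM or more there with 0 fragments of Ddx3y, Eif2s3y, Kdm5d and Uty. In both PIC144 lines, female cells mixed into the culture are argued against by Xist at 0.0700% or less of the lowest PIC496 level. Reads carried over from the IDH1 WT libraries are argued against for PIC144-3 by its ratio of Ddx3y to Kdm5d fragments, 3.28 (95% interval 2.67 to 4.04). For PIC144-1 the ratio does not decide, since its 2.36 (1.75 to 3.21) overlaps that of PC308-1 (1.61 to 1.82), and of no other IDH1 WT line. Chosen after their values were seen, H2-Ab1, Cox4i2 and Gpr17 were at 12.8, 10.9 and 30.9 FPKM in PC308-1, where Ddx3y was at 10.2 FPKM. In PIC144-1 they were at 0, 0.0488 and 0.189 FPKM, with Ddx3y at 0.580 FPKM. This argues against carry-over from PC308-1 as the whole source in PIC144-1. Loss of the Y chromosome in most PIC144 cells may account for the low levels and was not tested. Such a loss alone would not change the ratio of Ddx3y to Kdm5d in the cells that keep the Y chromosome. It therefore leaves the 3.28 of PIC144-3, against 1.503 to 1.715 in the IDH1 WT lines, without an account. The ratio cannot decide this, since that of PIC144 cells with a Y chromosome was not measured.

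For the count of genes changed, 1 of the 35 splits of the lines gave a result as large, the real split with 15 genes, and the highest other split gave 3. This argues against chance for the count at the main setting only if the 7 lines are independent. It does not exclude chance, since 1 of 35 is the smallest share possible. Lines sharing a number in their name could break this independence, and PC134-0 and PC326-1, with the highest correlation of any pair (0.983) and like shifts of chromosomes 12 and 13, put it in doubt. Chance is not argued against for genes at an unadjusted p under 0.05, of which the real split gave 1719, PIC144-3 with the 3 IDH1 WT lines against the rest gave 2241, and PIC144-1, PIC496-3, PIC496-4 and PC308-1 against the rest gave 1825. The count of 15 was 0 without PC134-0 (698 genes at an unadjusted p under 0.05), where the filter also left 5 of the 15 genes untested, 3 without PC134-0 with the 13379 genes kept (742 genes), and 0 with limma voom (1643 genes). For genes differing between lines of a genotype, 1 of 100 groupings gave as many, the real one, both for the IDH1 mutant lines (10801 genes, highest other 4551) and the IDH1 WT lines (8215 genes, highest other 6638).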

How the results depend on the processing

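Chosen after seeing the data were voom on recovered fragments, leaving out both PIC496 lines, autosomal genes only and lines left out with tested genes kept. Cgas stayed lower under all 26 alternatives (log2 difference -2.15 to -1.16), and its exact permutation p stayed at 0.0571 or above, although leaving out a line, averaging lines or leaving out both PIC496 lines allows no p under 0.05. Its limma p before adjustment lay above 0.05 once, without both PIC496 lines (-1.16, p = 0.0541). Its adjusted p ranged from 0.000283 to 0.833 and was under 0.05 only with line weights and in the 3 fits over 21 libraries, which repeat the same lines.

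The count of genes changed was 15, and 3 with no filter, 8 with the stricter filter, 6 (0 higher, 2 shared with the 15) with lines sharing a number averaged, 647 with line weights, 4 without both PIC496 lines and 0 with voom (1643 genes at an unadjusted p under 0.05). Leaving out lines or replicates gave 0 to 29. Without an IDH1 WT line the filter left 5 of the 15 untested. With tested genes kept it was 3 to 48. Over 21 libraries it was 552 with the line as a random effect, 4266 with libraries as independent samples and 440 with the replicate block and the line as a random effect. The replicate numbers were not treated as pairs in the main fit. The correlation of deviations from line means was 0.0298 on average between same-numbered libraries (-0.125 to 0.292). The -0.0148 between others follows from taking deviations from line means and is no separate comparison. Of 21 libraries, 12 correlated best with their own number out of 3 numbers, so a shared effect of the replicate number is not excluded. Fewer lines and the filter explain smaller counts in part. The rest was not tested.

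The count of lists called was 8, and 0 with an estimated correlation (0 at an unadjusted p under 0.05), 3 with line weights, and 2 to 12 when leaving out lines or replicates. Interferon-stimulated genes stayed lower under all 28 alternatives (medians -1.16 to -0.37) and lost their call with an estimated correlation (-0.78, adjusted p = 0.543). Besides estimated correlation and lines left out, calls ended for pyrimidine synthesis with the stricter filter (adjusted p = 0.0664), TPM (0.0662) and line weights (0.0736), for the 2-oxoglutarate list with quantile normalization (0.0881) and weights (0.0736), for neurons with no filter (0.299), TPM (0.0628) and weights (0.0736), and for proliferation (0.135) and oligodendrocyte progenitors (0.623) with weights. Without both PIC496 lines they ended for class I genes (0.144), the 2-oxoglutarate list (0.476), pyrimidine synthesis (0.195) and proliferation (0.144), while neural stem (0.0347) and mesenchymal genes (0.000528) were called. Silencing of endogenous retroviruses was called with pseudocount 0.1 (0.0491), no filter (0.00946), protein-coding genes (0.0339), the random effect (0.0431) and independent libraries (0.0393). Neural stem genes were called under 6, mesenchymal genes under 4 and astrocytes under 2 of 28 alternatives. Genes differing between the IDH1 WT lines ranged from 2523 without PC308-1 to 7657 when leaving out lines or replicates.

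Directions turned only for lists and genes that were not called, and none was called after turning. Cytosolic DNA sensing turned by camera with TPM (-0.037), quantile normalization (-0.017), line weights (-0.032), the random effect with or without the block (0.048), without both PIC496 lines (-0.044), and when leaving out lines or replicates (-0.038 to 0.082). Without both PIC496 lines, chemokines and cytokines (0.43), DNA methylation and TET (-0.012), histone demethylases (-0.092), Cldn11 (0.17) and Flt1 (0.77) turned. Histone demethylases also turned with the stricter filter (0.0044), TPM (-0.040), quantile normalization (-0.013) and autosomal genes (-0.086). Quantile normalization turned hypoxia-response genes (-0.016), glioma driver genes (0.074) and Flt1 (0.040). Over lines or replicates left out, chemokines and cytokines ranged from -0.37 to 0.16, histone demethylases from -0.016 to 0.11, hypoxia-response genes from -0.021 to 0.24, glioma driver genes from -0.026 to 0.14, H2-Ab1 from -2.09 to 0.12, Cd68 from -0.88 to 0.29 and Flt1 from -0.60 to 0.26. The cause was not tested. A test planned for counts was not run, since the values are FPKM. Beside the fit with the line as a random effect, the replicate block moved the lists called from 11 to 9.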

Other observations

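The counts per chromosome and the genes named in this part were chosen after their values were seen, and the test on parts of chromosomes 12 and 13 was written before its result was seen. PIC144-1 had 4.59 FPKM of Aim2, a DNA sensor of the inflammasome, against 0.0176 FPKM or less in the other lines, and 1.14 FPKM of Ifi204, a DNA-binding interferon-inducible protein, against 0.0562 FPKM or less. Myc, the growth transcription factor, was at 50.2 to 271 FPKM in the IDH1 mutant lines and 25.4 to 29.7 FPKM in the IDH1 WT lines, and Trp53, the tumour suppressor, was at 16.1 FPKM in PIC496-4 and 1.24 FPKM in PIC144-3, with 1.40 to 1.69 FPKM in the IDH1 WT lines. Neither passed over all genes.

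Among genes at an unadjusted limma p under 0.01, 25 of the 262 lower genes lay on the X chromosome, where 9.49 were expected (Fisher's exact test, adjusted p = 0.000262 over 40 tests), and 42 lay on chromosome 2, where 20.8 were expected (adjusted p = 0.000262). The median log2 deviation from the mean of the lines over the 843 tested genes of chromosome 2 with a mean of at least 2 FPKM was itself shifted in single lines, at 0.198 in PC134-0, 0.163 in PC326-1, -0.104 in PC308-1, -0.155 in PIC144-3, -0.0499 in PIC144-1, 0.0212 in PIC496-3 and 0.0266 in PIC496-4, so the count on chromosome 2 cannot be read as an effect of genotype. Sex may play a part in the count on the X chromosome, since Xist was at 0.0139 FPKM or less outside both PIC496 lines. Both PIC144 lines, with Xist at 0.00567 FPKM or less, were like the IDH1 WT lines in this. The count was not repeated without both PIC496 lines, so the part of sex is not known. Genes of the X chromosome were also shifted in single lines, at 0.112 in PC308-1, -0.0816 in PC326-1 and -0.0706 in PIC496-4, with the other lines between. The count on the X chromosome therefore cannot be read as an effect of genotype either. Fewer lower genes than expected lay on chromosome 3 (3, expected 13.2, adjusted p = 0.0141), chromosome 12 (1, expected 9.57, adjusted p = 0.0141) and chromosome 11 (9, expected 20.9, adjusted p = 0.0302). Chromosome 12 was shifted in single lines too, at -0.53 in PC134-0, -0.54 in PC326-1 and 0.52 in PC308-1, so its count cannot be read as an effect of genotype. Neighbouring genes are not independent in these tests.

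A hypothesis is that the shifts of chromosomes 12 and 13 come from gain or loss of the whole chromosome in some lines. Both parts of each chromosome, split by gene order, would then shift alike. In PC134-0, PC326-1 and PC308-1 the smallest shift of a part in the direction of the whole was 0.490 for chromosome 12 and 0.252 for chromosome 13, consistent with a change of the whole chromosome. DNA copy number was not analysed here.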
